A study of Phanerodontia chrysosporium with 12 samples.

How the data were processed

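RNA was sequenced from 12 cultures of Phanerochaete chrysosporium RP78, 3 at each of T0, 1 h, 3 h and 6 h after oak extractives were added to 100 µg/ml from a 200 mg/ml stock in DMSO. Per the labels' protocols and the design text, total RNA was extracted with a kit for soil samples, libraries followed standard Illumina protocols and the sequencer was a HiSeq2500. Samples were grouped by the treatment in their labels, which call the 3 cultures of a time biological replicates.

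The authors deposited a table per sample with 13602 protein IDs. Per the file headers, each table holds counts of unique gene reads, counts of total gene reads and RPKM values. The deposited RPKM values follow from counts scaled to the total gene reads of the library. With the gene lengths recovered from counts and RPKM, they were matched to within a relative gap of 2.1e-08 in every library. The counts were used as deposited, and the RPKM values served only to recover the lengths. The lengths were known for 13120 IDs with a read in at least 1 library (median 1207.5 nt), and 62.9% were multiples of 3. The header of the table of 3 h replicate 1 names paired reads. The aligner, the counting tool, the genome build, the annotation and the use of strand are not given in the sources used here. Of the total gene reads, 0.641% to 1.06% per library were not unique gene reads but reads shared between gene models.

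Total gene reads per library were 9127928, 3007296 and 2498521 for T0 replicates 1 to 3, 6999282, 2137932 and 3002663 at 1 h, 10697807, 5439594 and 10217840 at 3 h, and 6284822, 5433973 and 9291797 at 6 h. Shares of a single library are given with 95% Wilson intervals, and a count of 0 with the level that 3 counts would give. Replicates were compared before averaging. The smallest ratio of the spread between replicates to sampling noise was 3.82 (3 h replicates 1 and 3), so no pair agreed within sampling noise and all were kept as separate samples.

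Total gene reads were tested in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr, 11813 genes kept). All 12 libraries entered each fit with the group as the only term, which left 8 residual degrees of freedom and a common biological coefficient of variation of 0.333. Comparisons were 1, 3 and 6 h against T0, 3 h against 1 h, 6 h against 3 h and a joint test of the 4 groups. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. Levels are CPM of the TMM-scaled library size, and shares of reads leave out the 2 dominant models. Standard errors (SE) of edgeR fold changes are back-calculated, as the size of the log2 fold change over the square root of the F statistic. Overlaps of calls and correlations of fold changes were set beside 20 simulations without a change and beside the overlap of independent lists. Each simulation drew all 12 libraries anew, T0 included, around the T0 levels. Lengths were compared with 2-sided permutation tests, for the closing section against genes drawn from the same of 20 bins of read number, and shared reads with Fisher's exact tests. The scripts were tested on simulated counts with 200 genes changed by known folds at each of 1, 3 and 6 h. Of 4-fold changes, 60.6% were recovered at 1 h, 64.3% at 3 h and 63.3% at 6 h against T0, and of 2-fold changes 8.16%, 5.00% and 4.08%, with 11666 genes tested.

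The tests, the samples in each fit, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were to be those with the largest changes among called genes whose groups do not overlap and that reach 10 CPM, with the most abundant T0 gene as a depth reference. The files do not pair the IDs with names, and no annotation was used here, so the rule's fallback applied. It takes the 2 IDs that rose most and the 2 that fell most over the comparisons with T0, and protein 3014073 as the reference. Protein 2891358 was added after its values were seen. For the same reason the 27 gene lists planned (among them cytochrome P450s, glutathione transferases, transporters, peroxidases and heat shock proteins) were not tested.

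Fixed at the same time were these other settings: DESeq2 size factors, upper quartile scaling, no filter on low counts, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a fit of the 2 groups alone, the replicate number as a block, each library left out in turn, an adjusted p under 0.01 and a test against a 1.5-fold change. Added after the data were seen were unique reads, leaving out the dominant models, their log2 share as a covariate, 3 libraries left out together, reads thinned to 729521 per library and removal of each library's trend on gene length.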

Results

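Phanerochaete chrysosporium is a white-rot basidiomycete that degrades lignin and is used to study how wood-decay fungi cope with the defence compounds of wood. The series asked how its transcriptome responds to oak extractives, the acetone-soluble fraction of Quercus petraea heartwood. Mycelium of the homokaryotic strain RP78 was grown without shaking for 4 days at 37 °C in 20 ml of minimal medium. Extractives dissolved in DMSO were then added to 100 µg/ml. Mycelium was harvested at once (T0) or after 1, 3 or 6 h, with 3 biological replicates per time, and the RNA of the 12 cultures was sequenced. The T0 cultures also received the extractives, so every comparison was between times after the addition. Cultures given DMSO alone for 1, 3 or 6 h were not analysed here.

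The count tables listed 13602 gene models by numeric protein ID, of which 482 had no read in any library and 11813 were tested. Total gene reads ran from 2137932 in 1 h replicate 2 to 10697807 in 3 h replicate 1. A pair of short gene models took much of this depth. Protein 3014073 (650 nt), the most abundant model at T0, held between 2.81% and 57.3% of the reads of a library. Protein 2891358 (156 nt), singled out after its values were seen, held between 0.314% and 8.61%. Together they took 34.0% ± 25.8 (SD, n = 3) of the reads at T0, 40.2% ± 28.4 at 1 h, 7.64% ± 6.98 at 3 h and 14.9% ± 3.74 at 6 h. The groups overlapped, since T0 replicate 1 lay at 4.311% (95% Wilson interval 4.297% to 4.324%) and 3 h replicate 2 at 15.68% (15.65% to 15.71%). Protein 3014073 did not pass the test at 3 h against T0, with a log2 fold change of -2.79 and an adjusted p of 0.151 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The reads left for all other models ran from 729521 in 1 h replicate 2 to 10364009 in 3 h replicate 1, so low transcripts were measured least precisely in replicates 2 and 3 of T0 and of 1 h. A count of 0 allowed a level of up to 2.90 CPM (reads scaled to library size) in 1 h replicate 2 and 0.195 CPM in 3 h replicate 1. These intervals and limits cover counting error only.

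**Figure D1:**
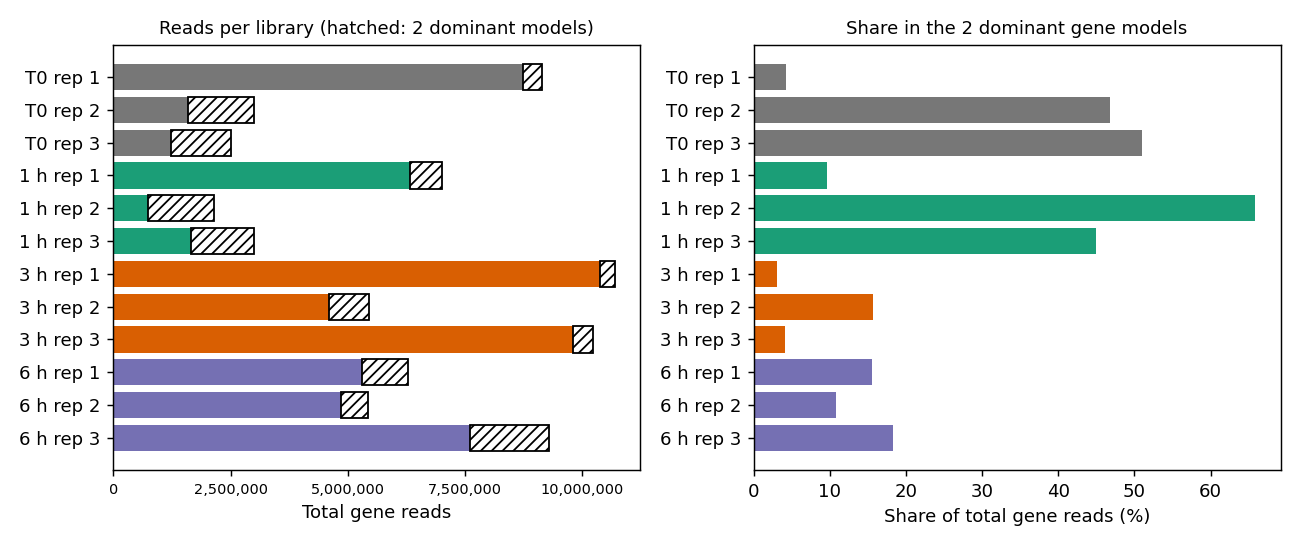
Total gene reads of each library (left, the hatched part being proteins 3014073 and 2891358) and the share of reads in these 2 models in percent (right), for 3 replicates at T0, 1 h, 3 h and 6 h. The share reached 65.9% in 1 h replicate 2 and lay at 3.12% in 3 h replicate 1.

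After the extractives were added, 1424 genes (12.1% of those tested) differed among the 4 times in the joint edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The genes called against T0 at 1, 3 or 6 h came to 1728. The IDs were not paired with gene names in the files, so genes are described by their time course, level, length and share of the reads, and 4 models picked by the size of their change are given by ID. The joint count was 924 without T0 replicate 1, 942 without 1 h replicate 1, 886 without 1 h replicate 3, 912 without 3 h replicate 1 and 2542 by DESeq2.

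**Figure D2:**
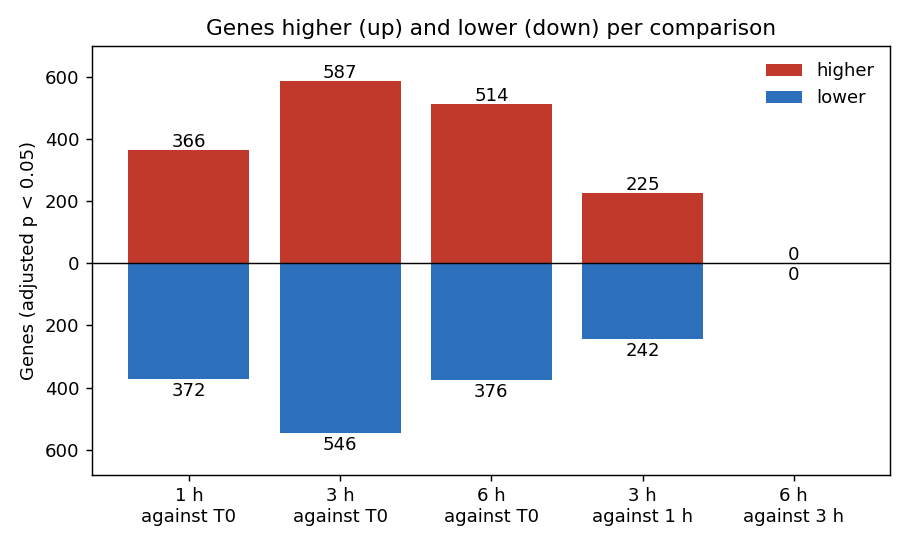
Number of genes higher (bars up) or lower (bars down) in each comparison at an adjusted p under 0.05 in the edgeR quasi-likelihood test, with 3 libraries per group. The bars show 587 higher and 546 lower at 3 h against T0, and 0 for 6 h against 3 h.

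The first comparison asked which transcripts had changed within 1 h. Genes that rose and genes that fell were about equally many at 1 h, with 366 higher and 372 lower than at T0. The 366 genes that rose had a median log2 fold change of 1.52 (quartiles 1.20 and 2.01), and 26 of them rose at least 8-fold. The 372 genes that fell had a median of -1.36 (quartiles -1.73 and -1.11). The genes that rose held 2.35% ± 0.255 (SD, n = 3) of the reads outside the dominant pair at T0 and 7.58% ± 0.839 at 1 h, and those that fell held 8.56% ± 1.69 and 2.94% ± 0.271, sums that follow from how the genes were chosen. Protein 7087 (1746 nt), the named gene with the largest rise at 1 h, went from 13.9 ± 7.89 CPM at T0 to 507 ± 111 CPM at 1 h (SD, n = 3). Its log2 fold change was 5.25 (SE 0.489), or 38.1-fold, with an adjusted p of 4.62e-05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of all tested genes, called or not, 24.6% had the 3 libraries at 1 h all above or all below the 3 at T0, which chance gives for 10% of independent genes with 3 against 3. Genes that shift together within a library can move this share away from 10% without a change between times. The number of genes changed was 342 without T0 replicate 1, 1432 without T0 replicate 2, 316 without T0 replicate 3, 319 without 1 h replicate 1 and 233 without 1 h replicate 3. DESeq2 called 1356 genes, and a fit of the 6 libraries of both groups alone called 472.

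At 3 h, 587 genes were higher and 546 lower than at T0. The genes that rose had a median log2 fold change of 1.55 (quartiles 1.18 and 2.04) and went from 4.22% ± 0.386 of the reads outside the dominant pair at T0 to 7.85% ± 1.12 at 1 h and 14% ± 0.648 at 3 h (SD, n = 3). The genes that fell had a median of -1.25 (quartiles -1.62 and -1.02) and went from 11.9% ± 0.778 at T0 to 6.80% ± 0.285 at 1 h and 4.39% ± 0.184 at 3 h. The sums of both sets at T0 and 3 h follow from how the genes were chosen. Protein 3023196 (1332 nt) was at 2.84 ± 1.11 CPM at T0, 15.2 ± 1.93 CPM at 1 h and 134 ± 71.2 CPM at 3 h. It rose 45.7-fold by 3 h, a log2 fold change of 5.51 (SE 0.512) with an adjusted p of 2.46e-05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). At T0 it had 41, 8 and 3 reads in replicates 1 to 3, so the size of its rise against T0 at any time rests on few reads there. Protein 3019667 (1501 nt) went the other way, from 57.7 ± 25.1 CPM at T0 to 3.01 ± 0.929 CPM at 3 h. Its log2 fold change of -4.19 (SE 0.552), or 18.3-fold, had an adjusted p of 0.000326 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of all tested genes, 29.4% had groups that did not overlap, against 10% by chance if genes were independent, which they are not. With the trend of each library on gene length removed, an alternative chosen after the data were seen, 597 genes were higher and 887 lower, and the median log2 fold change of all genes went from 0.03 to -0.09. The number changed was 685 without T0 replicate 3, 484 without 3 h replicate 1, 604 without 3 h replicate 3, 735 with the 6 libraries alone and 631 with the share of the dominant pair as a covariate. Whether 3 h had more changed genes than 1 h depended on the setting, with 1432 at 1 h and 1138 at 3 h without T0 replicate 2, 502 and 484 without 3 h replicate 1, and 748 and 631 with that covariate.

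At 6 h, 514 genes were higher and 376 lower than at T0, so genes that rose outnumbered those that fell. Their median log2 fold changes were 1.50 (quartiles 1.22 and 1.97) and -1.32 (quartiles -1.72 and -1.06). The 514 genes that rose went from 4.24% ± 0.573 of the reads outside the dominant pair at T0 to 12.7% ± 2.44 at 6 h, and the 376 that fell went from 7.96% ± 0.970 to 2.70% ± 0.259 (SD, n = 3). These sums follow from how the genes were chosen. Protein 5806 (324 nt) was at 245 ± 104 CPM at T0, 124 ± 27.9 CPM at 1 h, 14.3 ± 9.32 CPM at 3 h and 10.5 ± 5.52 CPM at 6 h. Its log2 fold change at 6 h was -4.56 (SE 0.503), or 23.5-fold, with an adjusted p of 0.000133 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Protein 3023196 stayed at 117 ± 46.0 CPM at 6 h, 39.6-fold above T0 with an adjusted p of 5.39e-05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of all tested genes, 25% had groups that did not overlap, against 10% by chance if genes were independent, which they are not. The number changed was 420 without T0 replicate 1, 484 without T0 replicate 3, 563 without 6 h replicate 2 and 509 (322 higher and 187 lower) without 6 h replicate 3, where 4.81% of the IDs at 0 to 5 reads had a read, against 32.1% to 56.7% in the other libraries. DESeq2 called 1492 genes and the 6 libraries alone gave 431. The count at 6 h was above that at 3 h without T0 replicate 2 (1251 and 1138), 3 h replicate 1 (663 and 484), 3 h replicate 2 (1001 and 951) or 3 h replicate 3 (737 and 604), and with the share of the dominant pair as a covariate (980 and 631).

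Whether the profile went on changing was tested directly. Between 1 h and 3 h, 225 genes rose and 242 fell, with median log2 fold changes of 1.54 and -1.58. Part of this was a return towards T0. Of the 366 genes higher at 1 h, 70 fell again by 3 h, and their median log2 fold change against T0 was 1.89 at 1 h, 0.05 at 3 h and 0.02 at 6 h. Of the 372 genes lower at 1 h, 78 rose again by 3 h, with medians of -1.63, 0.01 and 0.16. Independent lists of those sizes would share 7.5 and 7.09 genes, but the same 1 h libraries enter both comparisons, so part of the excess may come from them. The medians at 1 h and 3 h also follow in part from these calls, while no comparison with 6 h entered the choice. Protein 7087 belonged to the first set. It came down to 78.9 ± 14.6 CPM at 3 h, a log2 fold change of -2.68 (SE 0.421) against 1 h with an adjusted p of 0.002 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and was still 5.92-fold above T0 with an adjusted p of 0.00223 in that test.

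Other genes changed after 1 h. A set of 94 genes was higher at 3 h than at both T0 and 1 h, with a median log2 fold change against T0 of 0.11 at 1 h, 2.02 at 3 h and 1.80 at 6 h, and 84 of them were also called higher at 6 h. A set of 97 genes was lower at 3 h than at both, with medians of 0.06, -1.46 and -1.17, and 66 of them were also lower at 6 h. Independent lists would share 11.2 genes in each direction. Protein 3023196 was in the rising set, with a log2 fold change of 3.17 (SE 0.441) between 1 h and 3 h and an adjusted p of 0.00113 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). It was already called higher at 1 h against T0, with a log2 fold change of 2.34 (SE 0.515) and an adjusted p of 0.0143 in that edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. That call was lost in 5 of 28 alternatives (edgeR quasi-likelihood, DESeq2 or limma-voom, Benjamini-Hochberg adjusted p from 0.000245 to 0.13), among them those without T0 replicate 1 (0.075) and without T0 replicate 3 (0.0636). Proteins 5806 and 3019667 were in the falling set, with log2 fold changes of -3.15 (SE 0.473) and -2.64 (SE 0.548) and adjusted p-values of 0.00167 and 0.0132 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. At 1 h against T0 these 2 genes did not pass, with log2 fold changes of -0.98 and -1.55 and adjusted p-values of 0.198 and 0.0862 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The call of protein 5806 at 1 h was gained in 1 of 28 alternatives, the removal of the length trend, at a log2 fold change of -1.32 and an adjusted p of 0.0238 (edgeR quasi-likelihood, DESeq2 or limma-voom, Benjamini-Hochberg adjustment, range 0.0238 to 0.547). The call of protein 3019667 at 1 h was gained in 5 of 28 alternatives (edgeR quasi-likelihood, DESeq2 or limma-voom, Benjamini-Hochberg adjusted p from 0.0295 to 0.294). These were DESeq2 (0.0422), limma-voom (0.0295), the share of the dominant pair as a covariate (0.0424), and the fits without 1 h replicate 2 (0.048) or 6 h replicate 2 (0.0459). Its call between 1 h and 3 h was lost in 5 of 28 (same tools and adjustment, adjusted p from 4.83e-05 to 0.239). Among these were limma-voom (0.0607, log2 fold change -2.09), the fit without 1 h replicate 2 (0.0572, log2 fold change -2.13) and that with the share of the dominant pair as a covariate (0.239, log2 fold change -1.73). With that covariate the adjusted p of protein 3023196 between 1 h and 3 h was 0.0518 at a log2 fold change of 2.54 (edgeR quasi-likelihood, Benjamini-Hochberg adjustment, range 1.5e-09 to 0.0518). These sets were defined after the data were seen, and adjacent comparisons share the libraries of a time. The medians of the sets at 1 h and 3 h follow in part from the calls that define them. The 467 genes changed between 1 h and 3 h became 247 without 1 h replicate 1, 292 without 1 h replicate 2, 166 without 1 h replicate 3, 170 without 3 h replicate 1, 171 without 3 h replicate 3, 929 by DESeq2 and 152 with the share of the dominant pair as a covariate. The 148 genes that turned back became 97 without T0 replicate 1, 233 without T0 replicate 2, 71 without 1 h replicate 1, 53 without 1 h replicate 3, 72 without 3 h replicate 1 or replicate 3, 283 by DESeq2 and 76 with that covariate.

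**Figure D3:**
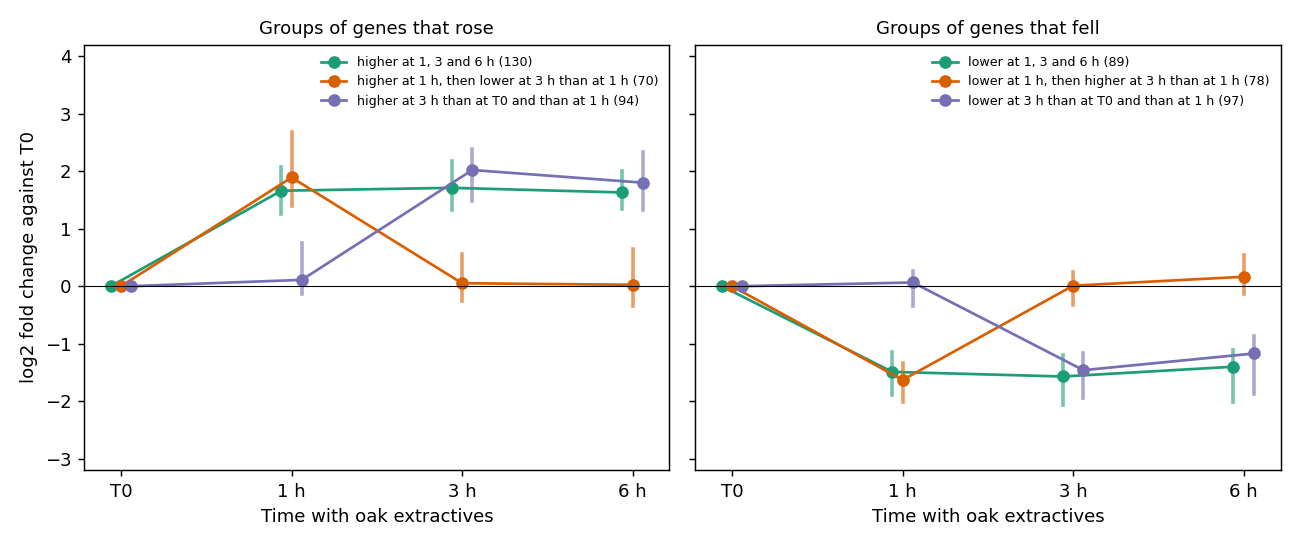
Median log2 fold change against T0 (points, with bars from the lower to the upper quartile of genes) at 1, 3 and 6 h for 6 sets of genes defined by their calls, with the number of genes in the legend. The 130 genes higher at each time stayed at 1.63 to 1.71, the 70 that turned back were near 0 by 3 h, and the 94 later ones were near 0 at 1 h. Medians at the times used to choose a set follow in part from that choice.

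Between 3 h and 6 h no gene passed the test. The edgeR quasi-likelihood test called 0 genes, with a smallest Benjamini-Hochberg adjusted p of 0.799 and 426 genes at an unadjusted p under 0.05. The 426 genes are fewer than chance alone would give among 11813 independent genes, so they are no sign of a further change. Of all tested genes, 10.9% had groups that did not overlap, near the share that chance gives for independent genes. limma-voom called 0 and DESeq2 called 8, all higher at 6 h. Each of the 4 named genes had an adjusted p of 0.996 between 3 h and 6 h in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and protein 3019667 had the widest difference of them, a log2 fold change of 1.00 (SE 0.522). In simulated data with the depth and spread of these libraries, 74.1% of 4-fold changes and 23.6% of 2-fold changes between 3 h and 6 h were called. Genes were changed at each time there, so this comparison held 189 genes changed 4-fold and 195 changed 2-fold. Many changed genes ease the adjusted threshold, so power with few changed genes would be lower. At 6 h against T0, with 98 genes of each size, 63.3% and 4.08% were called, which also rests on the T0 libraries. Smaller differences would mostly not be detected at this depth and spread.

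**Figure D4:**
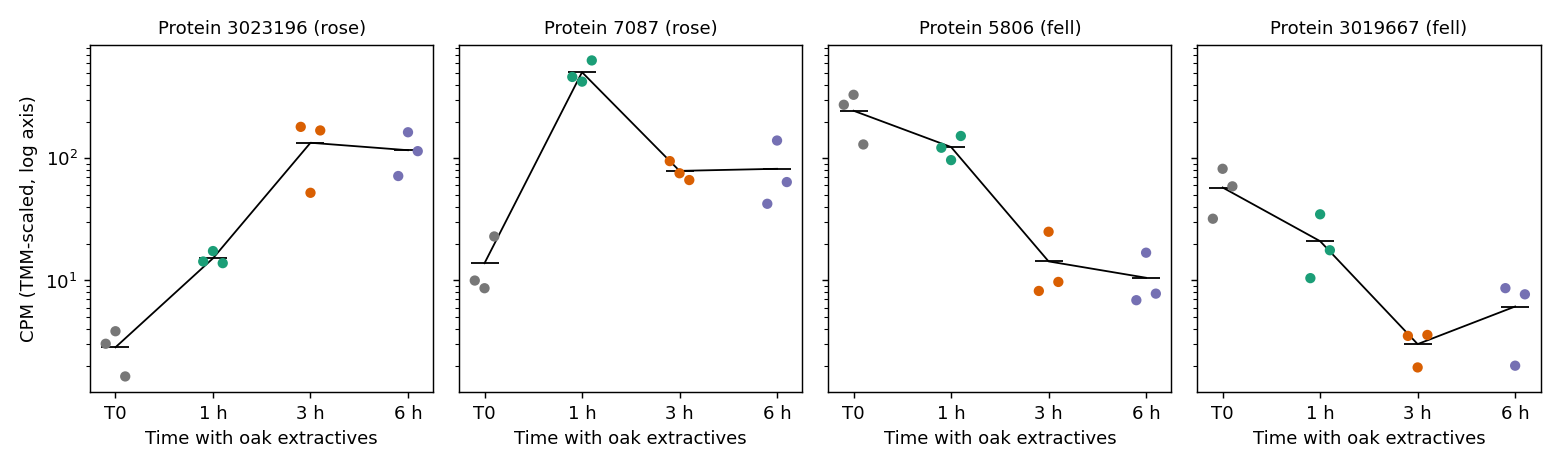
Level of proteins 3023196, 7087, 5806 and 3019667 in CPM on a log axis in each library (points) at T0, 1 h, 3 h and 6 h, with the mean of 3 replicates as a black line. Protein 7087 peaked at 507 CPM at 1 h and protein 3023196 reached 134 CPM at 3 h, while proteins 5806 and 3019667 were lowest at 10.5 CPM at 6 h and 3.01 CPM at 3 h.

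The responses at the 3 times shared many genes. At 3 h and at 6 h, 384 genes were higher in both and 281 lower in both, against 25.5 and 17.4 expected for independent lists of those sizes. At 1 h and 3 h, 182 were higher in both and 149 lower in both, against 18.2 and 17.2, and at 1 h and 6 h, 151 and 101, against 15.9 and 11.8. At all 3 times 130 genes were higher and 89 lower, against 0.791 and 0.547 for independent lists. The 130 genes had median log2 fold changes of 1.66, 1.71 and 1.63 at 1, 3 and 6 h, and the 89 genes had -1.49, -1.57 and -1.40. These medians follow in part from the choice of genes called at all 3 times. Across the 11813 tested genes, which are not independent replicates, the log2 fold changes at 3 h and 6 h had a Pearson r of 0.811 and a Spearman rho of 0.792. The comparisons share the T0 libraries. In 20 simulated sets of all 12 libraries, T0 included, no gene was changed and the mean r was 0.550. Since the simulated sets hold no real change, their count of 0 genes called in both is no measure of the overlap that shared libraries bring to real calls. They drew genes independently, with the same spread of a gene at all times. Shifts of a whole T0 library are thus left out, and the simulated values can understate what the shared T0 libraries bring. The covariance was 0.541 against 0.145 in the simulated sets, an excess of 0.397. For 1 h with 3 h, r was 0.598 (rho 0.591, simulated r 0.515) and the covariance exceeded the simulated value by 0.242, and for 1 h with 6 h, r was 0.551 (rho 0.548, simulated r 0.509) and the excess was 0.222. The 3 T0 libraries cannot be split into 2 sets of at least 2 each, so part of the overlap may come from them. The 219 genes called at all 3 times became 87 without T0 replicate 1, 421 without T0 replicate 2, 91 without T0 replicate 3, 107 without 1 h replicate 1, 93 without 1 h replicate 3 and 122 without 3 h replicate 1.

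Levels at T0 were higher in the genes that fell than in those that rose, to which the choice of these genes on the same T0 libraries contributes. The median T0 level was 82.2 CPM for genes lower at 1 h, 81.8 CPM for genes lower at 3 h and 75.2 CPM for genes lower at 6 h, against 25.7, 21.9 and 24.7 CPM for genes higher at those times and 22 CPM for all tested genes. At 3 h, 229 of the 546 genes that fell and 64 of the 587 that rose were at 100 CPM or more at T0. The difference in level was not tested, and neither was whether falls from a low level were harder to call at these depths.

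The lengths of changed genes differed from the rest, by amounts that depended on whether the length trend of each library was removed. The median length was 1616 nt for genes lower at 1 h against 1262 nt for the other tested genes, 1437.5 against 1266 nt at 3 h and 1634.5 against 1264 nt at 6 h. Genes that rose were shorter, with 1050 against 1282 nt at 1 h, 1164.5 against 1281 nt at 6 h and 1251 against 1276 nt at 3 h, where the direction turned (1332 against 1271 nt for genes not called) once the length trend of each library was removed. The 2-sided permutation tests of these 6 differences gave p = 0.00845 for genes higher at 3 h (adjusted p = 0.00845) and 1e-05, the smallest that 100000 permutations can give, for the others (Benjamini-Hochberg adjusted p = 1.2e-05). These tests treat genes as independent and measure the spread between genes, not between cultures. A library whose whole profile shifts with length can give such p-values without a change between times. These directions were the same with upper quartile scaling and DESeq2 size factors. Removing each library's length trend takes out a technical and a real trend alike, so it cannot tell them apart. With that trend removed, the difference for genes lower at 3 h was gone, with 1272 against 1271 nt for genes not called. The medians of genes higher and lower were then 1255 and 1335 nt at 1 h (1273 nt for genes not called) and 1240.5 and 1332 nt at 6 h (1274 nt), differences that were not tested. For the 389 tested genes with at least 10% of reads shared with another model, none of 6 Fisher's exact tests of their rate of calls passed adjustment (lowest adjusted p = 0.147, both for genes lower at 1 h, 1.29% against 3.21% of the rest, and for genes lower at 3 h, 2.57% against 4.69%).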

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

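The fits without the dominant pair, with its share as a covariate and with 3 libraries left out together, and the question of time or DMSO alone, were chosen only after the library totals were seen, and the test of calls in thinned reads after such calls were seen.

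The change since T0 differed between 1 h and 3 h for 467 genes in the direct comparison of these times (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Among the named genes, the log2 fold change at 3 h exceeded that at 1 h by 3.17 for protein 3023196, and it differed by -2.68 for protein 7087, -3.15 for protein 5806 and -2.64 for protein 3019667. Each of the 4 had 3 libraries at 3 h on one side of the 3 at 1 h. With the share of the dominant pair as a covariate the count was 152, the log2 fold changes of the 467 genes were 0.916 times as large (quartiles 0.805 and 1.04), and their standard errors 1.17 times as large. The count ran from 166 without 1 h replicate 3 and 170 without 3 h replicate 1 to 651 without T0 replicate 2, and was 247 without 1 h replicate 1, 292 without 1 h replicate 2 and 171 without 3 h replicate 3. Single libraries were not tested as outliers in groups of 3.

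Other splits of the libraries were tried. For the 4 groups together, 1 of 100 splits of the 12 libraries, the real one, gave as many as 1424 genes, and the highest other gave 463. The other splits were a random draw from many more, so a chance split is unlikely to give this count but is not excluded. For pairs of groups, 6 libraries make 10 splits, too few for a share under 0.05. In fits of 6 libraries the real split gave 472 genes at 1 h, 735 at 3 h and 431 at 6 h against T0, 610 between 1 h and 3 h, and 0 between 3 h and 6 h, and the highest other split gave 0, 0, 1, 0 and 0. In the first 4 only 1 split, the real one, reached the real count, and in the last all 10 did.

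The dominant pair took 34.0% and 40.2% of the reads at T0 and 1 h and 7.64% and 14.9% at 3 h and 6 h, with libraries that overlapped, and this could bear on the 1133 genes changed at 3 h. The tables argue against a distorted scaling, since 97.2% of these genes kept their call and direction without the pair. They also argue against a trend along the share of the pair as the whole cause, since with that covariate the median ratio of log2 fold changes was 0.959 (quartiles 0.870 and 1.05), while standard errors grew 1.11 times and 631 genes were called. In 10 random thinnings of every library to 729521 reads, 70.9% to 74.8% of the genes kept call and direction, so most calls did not need unequal read numbers. Thinning keeps the expected fold changes, so it cannot test a bias already present in the shallower libraries. The other calls were lost at a depth that lowers power, with standard errors of the called genes 1.14 times as large, which decides nothing either way. Unequal depth as a cause stays open. Time in culture or DMSO alone stays open and cannot be told apart from the extractives, because 0 libraries were from cultures kept for 1, 3 or 6 h without them. A response to the extractives stays open as the design's own explanation, untested for the same reason.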

How the results depend on the processing

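Of the settings below, those with the share of the dominant pair, 3 libraries left out together, unique reads, no dominant pair, thinned reads or no length trend were chosen after the data were seen, and the others were planned. The total counts per comparison kept within 1.5 times of those reported with DESeq2 size factors, upper quartile scaling, no low-count filter, the 5 CPM filter, limma-voom, unique reads, no dominant pair, thinned reads and no length trend. Counts in a single direction moved further in some of these, with 575 lower at 6 h against 376 by limma-voom, and, without the length trend, 384 lower between 1 h and 3 h against 242, 140 lower at all 3 times against 89 and, at 3 h, 887 lower against 546 beside 597 higher against 587. The cause was not tested unless named.

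DESeq2 called 1356 genes at 1 h, 850 lower at 3 h against 546, 1492 at 6 h, 929 between 1 h and 3 h, 8 between 3 h and 6 h, 2542 among the 4 groups and 444 at all 3 times. Fits of the 2 groups alone, with fewer samples, gave 472, 735 and 431 at 1, 3 and 6 h and 102 at all 3 times. An adjusted p under 0.01, a stricter limit, gave 219, 433 and 320, with 148 between 1 h and 3 h, 570 among the 4 groups and 58 at all 3 times. The test against a 1.5-fold change gave 217, 385 and 303, with 145 between 1 h and 3 h and 50 at all 3 times. The share of the dominant pair as a covariate gave 631 at 3 h and 152 between 1 h and 3 h. Without T0 replicate 3, 1 h replicate 2 and 6 h replicate 3 together, 216, 720 and 281 genes were called at 1, 3 and 6 h, 647 among the 4 groups and 50 at all 3 times, with 134 higher between 1 h and 3 h against 225. With each library left out in turn, the counts ran from 233 to 1432 at 1 h, 484 to 1218 at 3 h, 420 to 1251 at 6 h, 166 to 651 between 1 h and 3 h, 0 to 1 between 3 h and 6 h, 886 to 1888 among the 4 groups and 87 to 421 at all 3 times. The lowest were without 1 h replicate 3, 3 h replicate 1 or T0 replicate 1, and leaving out T0 replicate 2 gave the highest except at 3 h and between 3 h and 6 h. The 148 genes that turned back were 73 with the 3 libraries left out, 52 at the stricter limit and 49 against a 1.5-fold change.

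The replicate block gave 611, 976 and 712 genes at 1, 3 and 6 h, 343 between 1 h and 3 h, 0 between 3 h and 6 h, 1180 among the 4 groups and 182 at all 3 times. Of 18 same-numbered pairs of libraries, 5 deviated together with r over 0.1 (range -0.279 to 0.412), so the numbers were not taken to pair the samples across the series. The 3 same-numbered pairs of T0 with 3 h were all over 0.1 (0.347, 0.412 and 0.199), which no other pair of times showed. Differently numbered pairs of T0 with 3 h ran from -0.442 to 0.328. Of 12 libraries, 7 correlated best with their own number, some of which chance alone would give. This is at most a hint from the data and not from the design. The block moved no count by more than 1.5 times.

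With the length trend removed, the median of all genes between 3 h and 6 h went from -0.02 to 0.09. For the named genes, 431 of 448 values kept their side of the threshold, 11 lost it, 6 gained it and 0 reversed. Depth limits low genes most in 1 h replicate 2. The gene list tests, the joint test against a 1.5-fold change and pseudocounts were not run.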

Other observations

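The removal of the length trend and the test of length against genes matched for reads were chosen only after the lengths of the called genes were seen, the parts by time of the latter after its result, and the parts by time of the test on close IDs after the counts of close pairs.

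The share of reads held by genes that changed within 1 h went partway back, to which the choice of these genes on the 1 h libraries contributes. The 366 genes higher at 1 h held 2.35% ± 0.255 (SD, n = 3) of the reads outside the dominant pair at T0, 7.58% ± 0.839 at 1 h, 5.29% ± 0.240 at 3 h and 4.49% ± 0.446 at 6 h. The 372 genes lower at 1 h held 8.56% ± 1.69, 2.94% ± 0.271, 4.75% ± 0.579 and 5.22% ± 0.430. The 587 genes higher at 3 h and the 546 lower at 3 h held 12.0% ± 2.81 and 5.13% ± 0.788 at 6 h, near their shares at 3 h.

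The difference in length between genes that fell and genes that rose has candidate explanations that are technical. One is that long genes have more reads and are called more easily. The tables argue against it as the whole cause at 1 h and 6 h, since genes lower at these times had a median length 1.17 and 1.18 times that of genes matched for read number (permutation p = 1e-04 for each, the smallest that 10000 draws can give). For genes lower at 3 h it stays open, since the ratio was 1.03 (permutation p = 0.22). It does not account for the genes that rose, which were shorter than genes matched for read number at 1, 3 and 6 h, at ratios of 0.76, 0.922 and 0.859 (permutation p = 1e-04, 0.0044 and 1e-04). The p-values of these permutations measure the spread between genes, not between cultures. A length trend between libraries stays open. The correlation of a library's deviation with gene length was 0.18, -0.445 and 0.329 in T0 replicates 1 to 3, a range of 0.773 and 3.16 times the gap of 0.245 between T0 and 1 h, although each T0 library was set against the other T0 libraries, which widens that range. With the trend removed, 657 of the 738 genes called at 1 h and 1062 of the 1133 called at 3 h were called again, so most calls do not rest on the trend. The removal takes out a technical and a real trend alike, so it cannot decide whether the length difference is technical.

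Genes with close protein IDs (at most 10 apart) tended to be called together. At 1 h, 18 close pairs were both higher against a mean of 8.23 in 10000 shuffles, 30 pairs were both lower at 3 h against 18.3, and 18 were both lower at 6 h against 8.67 (permutation p = 0.0027, 0.0076 and 0.0049, each 0.015 after adjustment over 6 sets). The other 3 sets did not pass. Among the 10219 genes with no shared read the excess was 14 against 6.68 at 1 h (permutation p = 0.0093, adjusted 0.056) and 12 against 6.86 at 6 h (permutation p = 0.048, adjusted 0.14). At 3 h it was 20 against 14.8 (permutation p = 0.12). The unadjusted p was under 0.05 at 1 h and 6 h, but none passed the adjustment, so shared reads stay open as the cause. What close IDs mean for position or kinship of the genes was not examined, so co-regulated neighbours may be a hypothesis to follow up with an annotation.

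The table of 6 h replicate 3 listed 2296 IDs at 0 and 116 with 1 to 5 reads, so 4.81% of its IDs at 0 to 5 reads had a read, against 32.1% to 56.7% in the other libraries. This table may have been filtered or made in another way, which was not tested, so a 0 in it need not mean an absent transcript. Without it 509 genes were called at 6 h against 890, and 0 between 3 h and 6 h. Protein 3014073 had 12.7 times the reads of protein 2891358 there and 6.65 to 8.93 times in the other libraries.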
